A study of Mus musculus with 4 samples.

How the data were processed

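Liver polyA RNA from ClockΔ19 mice that carried a driver and a doxycycline-repressed Clock transgene was sequenced at CT22, CT28, CT34 and CT40, with 1 library per time and 3 animals pooled per library, per the labels. Animals were held in 12 h of light and 12 h of dark before constant darkness. The genome build was mm9, per the submitters' processing notes. Junctions were found with the aligner RUM, per the file headers; its version and the rule by which the authors counted reads are not given in the sources used here.

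The authors deposited, for each library, a table with a lower and an upper value for every transcript, exon and intron, and a list of splice junctions. The deposited feature values carry no stated unit. They behaved as RPKM: multiplied by feature length, they fell on whole multiples of 1 step per library, within 0.05 read beyond rounding, for 99.96 to 99.97% of lower and 99.86 to 99.87% of upper transcript values above 0, and for 99.26 to 99.44% and 99.20 to 99.31% of those of introns. They were treated as RPKM, with the lower value read as uniquely mapped reads and the upper as including multi-mapped reads; this reading of the columns is inferred from the values. The step implied denominators of 27539200, 27546200, 24520700 and 26407600 reads. The junction files hold deposited counts of reads per junction. The library protocol does not mark strand, so genes that overlap on opposite strands cannot be told apart.

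Transcripts numbered 115699. RefSeq and Vega identifiers in the files were matched to symbols, 26042 through RefSeq and 53799 through Vega only, and 35854 transcripts without a symbol were left out. Each of the 24196 genes was represented by its transcript with the highest mean. Gene reads were scaled by TMM (edgeR 4.0.16), genes with a mean of at least 100 reads were kept, and counts under 3 were set to 3. Counts of 2-fold differences carry no test, because there is 1 library per time; 20 simulated tables gave the number from counting error. Ratios of named genes have exact conditional 95% intervals.

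The 24-h cosine model was planned on counts with edgeR. Because the deposited unit is RPKM-like, the main test was limma 3.58.1 (trend, F test of the 2 cosine terms) on log2 of the TMM-scaled value with a pseudocount of 0.1, a scale that understates changes of low genes; edgeR's quasi-likelihood test on recovered reads and DESeq2 1.42.0 were alternatives. R was 4.3.3. With simulated library noise of 0.249 log2 (SD), the limma step on 9069 genes found 24% of 2-fold and 97% of 4-fold changes, with 3.20% of its calls unchanged genes. The 2-fold range rule on the same simulated table called 319 unchanged genes. The simulated noise was independent between genes and equal in all libraries. In the real libraries the SD of log2 values about the gene means was 0.377 at CT22 and 0.194 at CT28. The simulated shares may therefore not hold for these data.

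Before the data were examined, 36 gene lists, the comparisons and the rule for named genes were fixed. The rule takes Clock, all measured core clock genes, the 15 genes with the largest 24-h amplitude among those with a 2-fold range, the 10 with the largest ratio in each direction for each 12-h pair, and up to 4 members of each list with the widest range. List medians are given as percentiles among 10000 random lists of the same size, matched on expression in 20 bins, as descriptions of these libraries. The matching did not cover GC content, transcript length or the tendency of list members to vary together. Of the 36 lists, 18 had a median log2 ratio below percentile 2.5 or above percentile 97.5 for either 12-h pair. An extreme percentile was therefore common and does not by itself set a list apart. Lists with under 3 measured members have no median, so they could not be extreme but are counted in the 36. Alternatives covered scaling, filters, multi-mapped reads, the unit, the transcript chosen and the size of change; those added after seeing the data used the 5' or 3' part of each transcript alone, junction counts, and values with a cubic trend in GC content and log length removed (GC content from a reference transcript was known for 99.8% of genes). Coordinates are mm9, from the files. Values of some single genes are not reported here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.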

Results

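Liver RNA from mice carrying the ClockΔ19 mutation was sequenced at 4 circadian times in constant darkness: CT22, CT28, CT34 and CT40, spaced 6 h apart. ClockΔ19 is a mutation of Clock, a gene of the transcription factor pair that drives the circadian oscillator. The animals also carried an Scg2:tTA driver and a tetO::Clock-HA transgene, a system in which doxycycline shuts the transgene off, and all of them received doxycycline at 30 ug/ml from 3 days before darkness. Each time point was 1 library made from the pooled RNA of 3 animals, so no difference below has a replicate check. Intervals of reads and ratios cover counting error only. Intervals of shares over genes treat genes as independent and leave out differences between libraries. The comparisons are between libraries, not between conditions. Gene reads recovered from the deposited values came to 17233391 at CT22, 19549708 at CT28, 18485563 at CT34 and 19800592 at CT40, and 9136 genes had a mean of at least 100 reads.

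The CT22 library differed from the others in signs of RNA quality and composition. Reads from the mitochondrial genome came to 17.7 per 100 gene reads at CT22, against 9.94 at CT28, 6.58 at CT34 and 6.32 at CT40. Intron reads came to 25.5 per 100 gene reads at CT22 and 20.7, 18.04 and 19.1 at the later times. Over 2110 long, well covered genes the median log2 ratio of read density in the 5' part of the transcript to that in the 3' part, split at the midpoint, was 0.19 at CT22, 0.47 at CT28, 0.70 at CT34 and 0.82 at CT40. Each exon was placed whole in the part that held its centre. A trend with GC content and transcript length held 30.9% of the variance of the CT22 library about the gene means, 1.17% at CT28, 15.8% at CT34 and 12.3% at CT40.

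Whether the libraries carried the labelled mutation was examined first. In Clock (NM_007715, mm9 chromosome 5, 76641202 to 76733573) nearly all informative junction reads skipped exon 19, an internal exon of 153 bases at 76660421 to 76660573 and the exon lost in this allele. Reads joining exon 18 to exon 20 numbered 28 at CT22, 31 at CT28, 44 at CT34 and 48 at CT40. Exon 19 was joined to its neighbours by 1 read on each side at CT28 and by none in the other 3 libraries. Over all libraries 151 reads skipped the exon, against 1 over each inclusion junction. With inclusion taken as the larger junction count, the skipping share was 99.3% (exact Clopper-Pearson 95% interval 96.4 to 99.98%). Exon 19 itself held 16, 12, 17 and 26 reads in time order, or 105, 78.4, 111 and 170 per kb. For single libraries the lower bound of the skipping share lay between 83.8% at CT28 and 92.6% at CT40. Total Clock expression was nearly level, with normalised counts of 1387, 1316, 1439 and 1383 in time order.

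**Figure D1:**
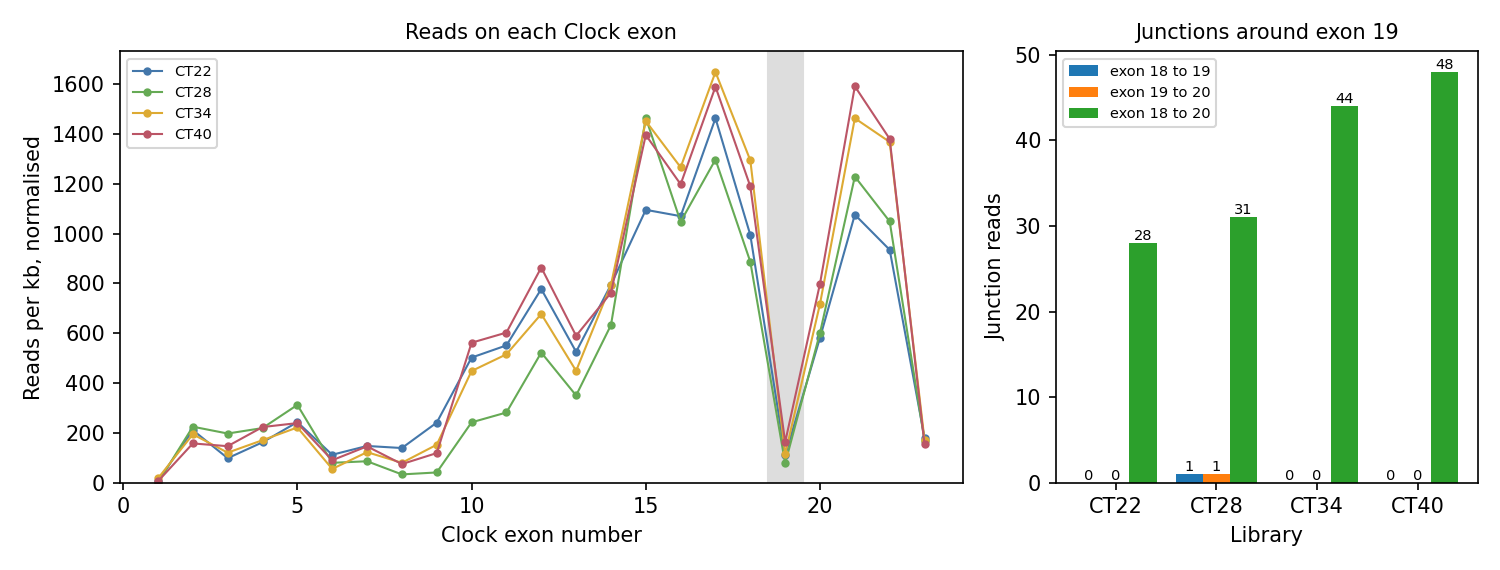
Left, reads per kb on each of the 23 Clock exons, divided by the library scaling factor, with 1 line per library and exon 19 shaded. Right, reads over the junctions around exon 19 in each library; the skipping junction holds 28 to 48 reads and each inclusion junction at most 1.

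Genes that varied over the 4 times included most of the oscillator. Npas2, a paralogue of Clock, had normalised counts of 15.6, 254, 657 and 195 from CT22 to CT40, a range of 42.1-fold (95% counting interval 25.3 to 75.6). Arntl, which encodes BMAL1, ran from 416 at CT22 to 1001 at CT34. Per2, a repressor of the oscillator, ran from 1338 at CT28 to 325 at CT40, Per3 from 313 at CT22 to 55.2 at CT34, and Nr1d1, which encodes the repressor REV-ERBα, from 408 at CT28 to 1901 at CT40. Of the 20 core clock genes measured, 11 had a range of at least 2-fold, and their median log2 range of 1.07 exceeded that of all 10000 random lists matched on expression. Dbp, a clock output gene, had too few reads for the gene counts, at 96.8, 55.2, 41.9 and 85.0, and 32.1% of its transcript overlaps another.

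Other groups with a wide range included the sex-biased liver genes and the systemically driven genes. Among 14 measured male-biased genes 10 had a 2-fold range, as had 8 of 11 female-biased genes and 10 of 11 genes known to follow systemic cues. Sult2a1, a female-biased sulfotransferase, had the widest range of the named genes at 46.0-fold (interval 31.0 to 71.3). Hepatocyte markers had a median log2 range of 0.49 (percentile 33.8 of the random lists), with a 2-fold range in 1 of 16 (Apoc1, at 2.00-fold). Mitochondrial respiration genes had a median of 0.36 (percentile 0.90), with 1 of 25 (Cox6c). In total 1184 genes (13.0% of those tested) had a 2-fold range and 86 had a 4-fold range, where simulated counting error alone gave 0. Simulated library noise of 0.249 log2 (SD), the size of the departure from a cosine, put 319 unchanged genes past the same 2-fold limit. That noise was independent between genes and equal in all libraries, so 319 is no bound for these data. Of the 1184, 608 were lowest and 419 highest at CT22; 419 were highest and 287 lowest at CT40. Without CT22 the count was 309, and without CT40 it was 735. With the trend in GC content and length removed, an alternative chosen after seeing the data, it was 777.

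**Figure D2:**
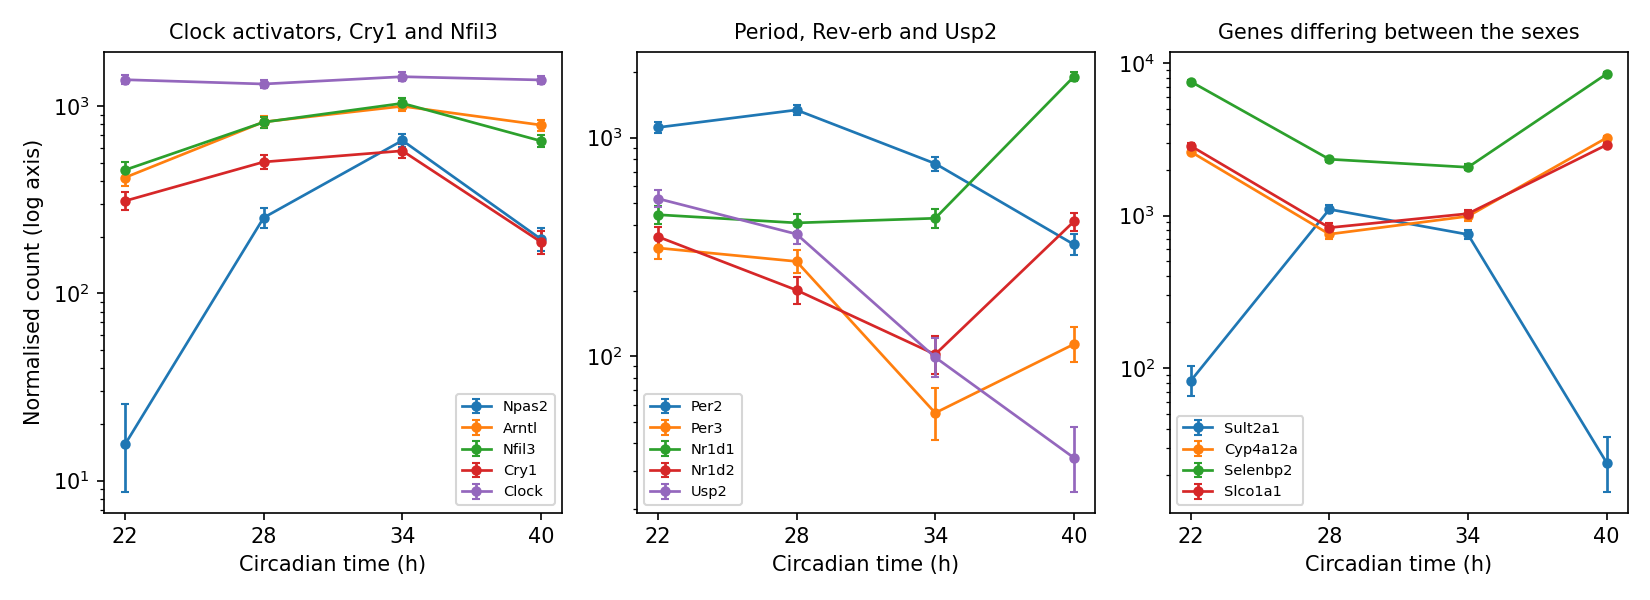
Normalised counts (log axis) against circadian time in hours for clock genes, the clock output gene Usp2 and genes that differ between the sexes. Bars are exact Poisson 95% intervals, with 1 pooled library per time. Npas2 is lowest at CT22 at 15.6 and highest at CT34 at 657, and Sult2a1 is highest at CT28 at 1098 and lowest at CT40 at 23.9.

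CT22 and CT34 lie 12 h apart, at opposite phases if the cycle is 24 h. The times run from CT22 to CT40, less than a full cycle, so the 24-h period was assumed and could not be tested. Genes higher at CT22 were led by Serpina4-ps1, a serpin pseudogene (16.5-fold, interval 14.6 to 18.7), and Cish, a suppressor of cytokine signalling (9.26-fold, 7.72 to 11.2). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 7.24-fold higher (6.77 to 7.76), Upp2, a uridine phosphorylase, 7.16-fold (6.80 to 7.54), and Hamp2, a hepcidin gene, 6.08-fold (5.83 to 6.35). The growth regulators Myc (6.63-fold) and Gadd45g (6.57-fold), the clock gene Per3 (5.68-fold, 4.24 to 7.73) and the clock output gene Usp2 (5.31-fold, 4.27 to 6.67) went the same way. Mup7 was 8.04-fold higher by uniquely mapped reads, but reads shared with other major urinary protein genes raise its total 185-fold, so its level is uncertain. Genes higher at CT34 were led by Npas2 (42.1-fold). They included Hspb1, a small heat shock protein (9.73-fold, 6.33 to 15.7), Sult2a1 (9.13-fold, 7.23 to 11.7), Egr1, an immediate early transcription factor (8.95-fold, 6.99 to 11.6), Cebpb, a liver transcription factor (8.55-fold, 7.14 to 10.3), Irs2, an insulin signalling adaptor (7.29-fold, 6.16 to 8.68), and the repressor Bcl6 (6.29-fold, 5.66 to 7.01). Multi-mapped reads bring the total of Hspb1 to 1.71 times its unique reads, so its level is less certain.

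By group, targets of the ROR elements were higher at CT34 in 6 of 6 measured members, 3 of them by 2-fold, with a median log2 CT22 over CT34 of -1.04 (percentile 0.02 of the random lists). Clock, among these 6, was nearly level, at 1.04-fold (interval 0.962 to 1.12). Targets of E-boxes, the sites the Clock protein binds, were higher at CT22 in 9 of 11 members, 3 of them by 2-fold, with a median of 0.55 (percentile 99.95). All measured ROR targets, and all measured E-box targets but Usp2 and Nampt, also belong to the core clock list. Male-biased genes were higher at CT22 in 12 of 14, 6 by 2-fold (median 0.65), and female-biased genes lower in 7 of 11, 5 by 2-fold (median -0.90). Cux2, a female-biased gene, went the other way and was 2.00-fold higher at CT22. Genes induced by glucocorticoids had a median of 0.50 (percentile 99.97), and genes of the fasting response under PPARα a median of -0.42 (percentile 0.58), with 4 of 22, among them Acot1 (7.23-fold higher at CT34) and Cyp4a14, 2-fold lower at CT22. Multi-mapped reads bring the total of Acot1 to 1.47 times its unique reads. Markers of liver endothelial cells were lower at CT22 in 10 of 10, 4 by 2-fold, with a median of -0.95, and Kdr went from 275 to 761. For Kdr, CT34 over CT22 was 4.82 in the 5' part, where CT22 had the lowest relative coverage, and 3.08 in the 3' part. Oit3 (4.24 and 2.04) and Cdh5 (3.54 and 2.09) went the same way, and Stab1 (1.76 and 2.49) the other. Scaled intron reads at CT22 and CT34 were 80.4 and 86.4 for Kdr, 96.0 and 67.4 for Cdh5, 29.5 and 26.0 for Oit3, and 229 and 330 for Stab1. Ribosomal protein genes were higher at CT22 in 35 of 41 (median 0.39), in the library with the most mitochondrial and intron reads; with the GC and length trend removed the median was 0.12. They were also higher at CT28 than at CT40 in 30 of 41, with a median of 0.22 (percentile 99.99), or 0.14 with the trend removed. In all, 282 genes were at least 2-fold higher and 366 at least 2-fold lower at CT22. With the trend removed these were 157 and 226, and scaling by total counts turned the balance, to 361 higher and 275 lower.

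**Figure D3:**
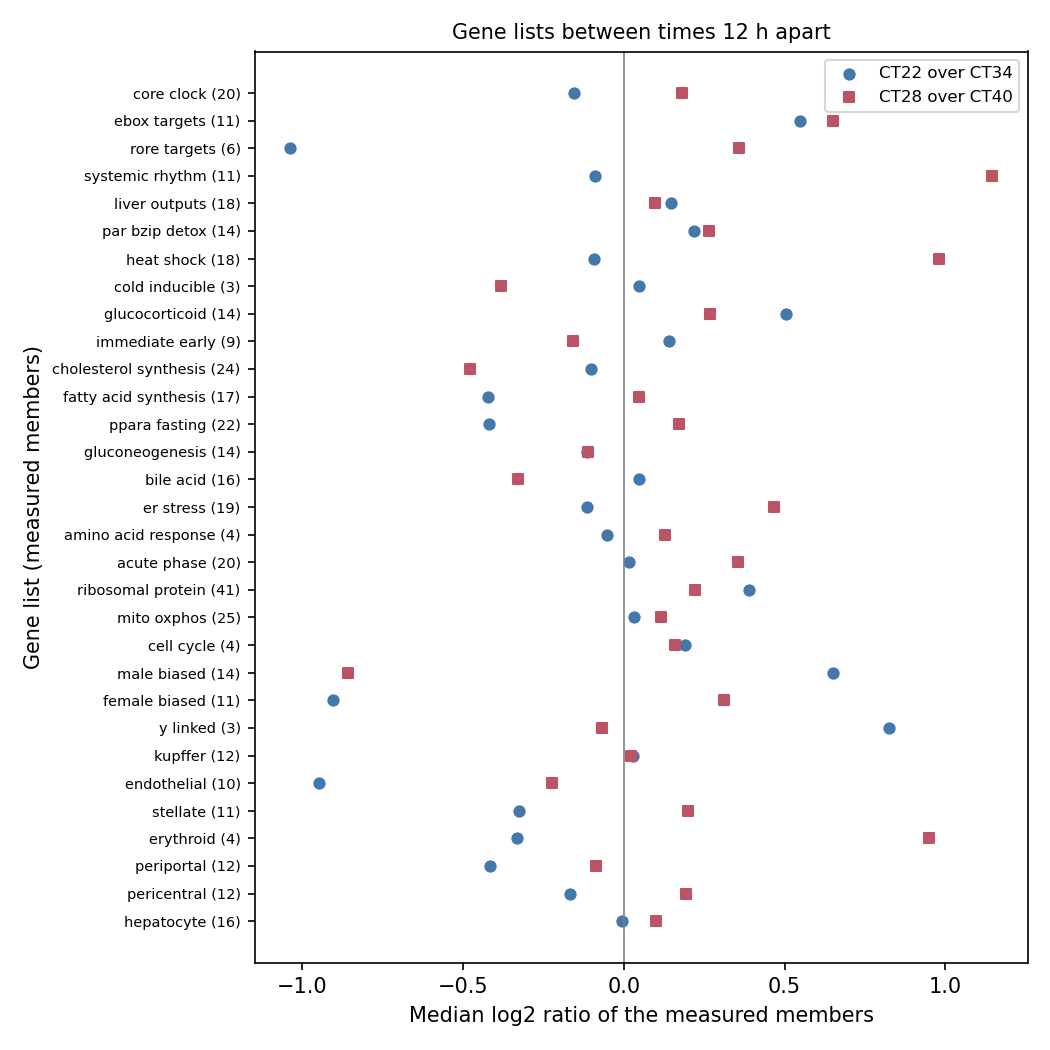
Median log2 ratio of the measured members of each gene list for CT22 over CT34 (circles) and CT28 over CT40 (squares), with the number of members in brackets. Male-biased genes lie at 0.65 and -0.86, and heat shock genes at -0.09 and 0.98.

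CT28 and CT40 are the other pair 12 h apart. Higher at CT28 were Sult2a1 (46.0-fold, interval 31.0 to 71.3), Usp2 (10.5-fold, 7.47 to 15.3), Angptl8, a regulator of lipoprotein lipase (8.15-fold, 7.57 to 8.79), Noct, a rhythmic RNA-decay gene (4.79-fold, 3.85 to 6.01), and Per2 (4.12-fold, 3.66 to 4.65). Higher at CT40 were Igfbp1, a binding protein for insulin-like growth factors (14.6-fold, 11.8 to 18.2), the metallothioneins Mt2 (6.49-fold, 6.10 to 6.91) and Mt1 (5.14-fold, 5.01 to 5.27), Nr1d1 (4.66-fold, 4.19 to 5.19), and C8a, a complement component (4.18-fold, 3.95 to 4.42). Selenbp2 was 3.63-fold and Cyp4a12a 4.29-fold higher at CT40; both are male-biased genes, and multi-mapped reads bring their totals to 2.38 and 2.14 times the unique reads.

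By group, heat shock genes were higher at CT28 in 18 of 18 measured members, 8 of them by 2-fold, and their median log2 CT28 over CT40 of 0.98 lay above all 10000 random lists. Hsp90aa1 was 3.37-fold higher (3.11 to 3.64; multi-mapped reads bring its total to 1.91 times the unique reads), and Hspa8, a constitutive chaperone, went from 25303 to 9436. Systemically driven genes had 7 of 11 members at least 2-fold higher at CT28 (median 1.15). Of these 7, 4 also belong to the heat shock list (Hsp90aa1 and, named after their values were seen, Hspa8, Hsph1 and Hspa1b), and Cirbp, a cold-inducible gene, was the other way, at 112 and 269. Endoplasmic reticulum chaperones and stress genes were higher at CT28 in 18 of 19, none by 2-fold, with a median of 0.47. Acute phase genes were higher in 13 of 20, with Saa2 3.92-fold (3.05 to 5.10). In the other direction, cholesterol synthesis genes were lower at CT28 in 23 of 24 members, 2 by 2-fold (Mvk and Mvd, the latter named after its values were seen), with a median of -0.48, below all random lists. Bile acid genes were lower in 13 of 16 (median -0.33, percentile 0.06). Male-biased genes were lower at CT28 in 13 of 14, 5 by 2-fold, with a median of -0.86, and Slco1a1, a transporter with few shared reads, was 3.49-fold higher at CT40 (3.24 to 3.78). Female-biased genes were higher at CT28 in 8 of 11, 4 by 2-fold, with a median of 0.31 (percentile 99.37), while Cux2 went 2-fold the other way, from 164 to 536. E-box targets were higher at CT28 in 8 of 11, 4 by 2-fold, with a median of 0.65, above all random lists, while Nr1d1 and Nr1d2 were at least 2-fold higher at CT40. Medians for the ROR targets, glucocorticoid-induced, core clock and PPARα fasting genes were 0.36, 0.27, 0.18 and 0.17 (percentiles 99.32, 99.83, 99.28 and 98.51). Of the 14 glucocorticoid-induced genes, 9 were higher at CT28, 3 by 2-fold, and 2 were lower by 2-fold, Mt1 and Mt2. Totals of 112 genes at least 2-fold higher and 100 at least 2-fold lower at CT28 were counted.

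**Figure D4:**
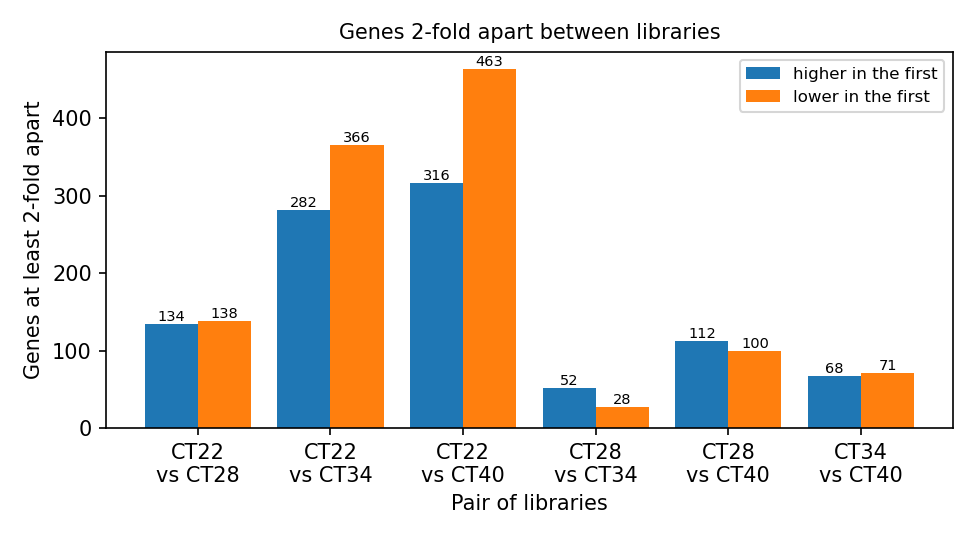
Number of genes at least 2-fold higher or lower in the first library of each pair. Pairs with CT22 hold the most genes, up to 316 higher and 463 lower against CT40, and CT28 against CT34 holds 52 and 28.

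A 24-h cosine was fitted to ask which genes followed the order of the times, with the period assumed. The model called 196 genes at an adjusted p of 0.05 or less (limma F test on the log2 scale, Benjamini-Hochberg), led by Sult2a1 (adjusted p = 1.28e-10 by limma) and Npas2 (2.76e-07). Among the core clock genes 7 were called, and 10 when adjusted over the list alone; Per3, Per2, Nr1d2 and Nr1d1 were called, with fitted peaks at 23.8, 3.00, 19.98 and 16.1 h of the cycle. Arntl was not called (adjusted p = 0.117 by limma), with a fitted peak at 9.83 h. Male-biased genes had 7 calls of 14, or 9 adjusted over the list alone, and heat shock genes 3 of 18, or 14 over the list alone. Cholesterol synthesis and ribosomal protein genes had 0 by either count. Called genes peaked within 3 h of CT22 in 72 cases, of CT28 in 34, of CT34 in 69 and of CT40 in 21, and their median peak-to-trough ratio was 3.55-fold. The model was fitted to values that still held the trend with GC content and length, which was largest at CT22. Whether that bias adds to the calls was not tested. The model has 1 residual degree of freedom, so the departure from a cosine stands in for the spread and a 12-h rhythm counts as noise. Counts by other tools ran from 78 (DESeq2) to 365 (edgeR), and 195 of the 196 were also called by edgeR on recovered reads.

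The share of variation in the 24-h terms was set beside that in other orders of the same libraries. Its median over genes was 80.5% in the true order (order-statistic interval 79.7 to 81.1%), 58.0% with CT28 and CT34 exchanged and 77.5% with CT34 and CT40 exchanged. Independent noise gives 2 of 3 parts on average, beside a mean over genes of 73.7% in the true order. Under such noise the median lies above the mean. It was not computed here, so the medians have no noise value beside them. A steady drift across the libraries would also put most of its variation in these terms. The shares of the 3 orders add to a fixed total, so they are not independent of one another. Among genes with a 2-fold range the median share was 80.4% in the true order and 83.4% with CT34 and CT40 exchanged.

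Intron reads were compared with exon reads for the genes that varied. They were summed over the introns of the chosen transcript, and exons of other transcripts or genes within these introns were not removed. Npas2 introns held 52, 435, 737 and 138 reads in time order and peaked at CT34 as its exons did, and introns of Cyp7a1 (867, 434, 52 and 347) and Cish peaked at CT22 with their exons. Other genes differed: Hsp90aa1 introns held 89, 12, 11 and 6 reads, with the peak at CT22, and its exons peaked at CT28. Scaled intron reads of Per2 were 520, 547, 492 and 635, highest at CT40, where its exons were lowest, though its unscaled intron reads were highest at CT22 (633). Those of Upp2 were 3833 at CT22, where its exons peaked, and 4382 at CT40, with 4670 and 4023 unscaled. Of 1059 genes with a 2-fold range and at least 50 intron reads, 655 had the same peak time in both (61.9%, exact interval 58.8 to 64.8%), against 28.4% when genes were shuffled. Library bias shared by the intron and exon reads of a gene could also raise this share and was not tested. Splice junctions numbered 152159, 157842, 158215 and 161970 in time order, and 48.9% of the 228997 junctions listed in any library were listed in all 4.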

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

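The tests of library drift, of the share of males and of shared reads over all male-biased genes were chosen only after the values they measure had been seen; those of 5' coverage and of GC content and length were set before their results were seen. Signal appeared in data that the comparisons do not use. Reads lay within the skipped Clock exon in every library: 16 at CT22, 12 at CT28, 17 at CT34 and 26 at CT40, although no more than 1 junction read joined it to either neighbour. Reads from the mitochondrial genome came to 17.7, 9.94, 6.58 and 6.32 per 100 gene reads in the same order.

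The CT22 library stood apart in the number of genes: 608 of the 1184 genes with a 2-fold range were lowest there. Loss of coverage confined to the 5' part as the whole cause is argued against by the 3' parts alone. There 81.5% of 583 of these genes (exact interval 78.1 to 84.5%) were still at least 2-fold below the highest other library. The genes were picked on reads that include the 3' parts, which raises this share. Of 1385 genes with a 2-fold range in the 3' parts alone, 45.9% were lowest and 40.1% highest at CT22. Coverage loss that reaches into the 3' part was not tested. Bias with GC content or transcript length may account for part. With that trend removed 48.8% of 607 genes kept the 2-fold difference, under the 50% set beforehand. The interval (44.7 to 52.8%) spans that limit, and it treats genes as independent. Of the 777 genes then left with a 2-fold range, 47.5% were lowest at CT22, so the tilt was not removed. Time of day is confounded with library and stays open.

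Male-biased genes were lower at CT28 and CT34, in pools that all held Xist (7748 to 11398 normalised counts) beside Y-linked reads (442 to 884), and so RNA of both sexes. Fewer males in the CT28 pool would need Y-linked reads to fall with them, and these were at 0.939 of the CT40 level (interval 0.847 to 1.04), where the 14 male-biased genes had a median of 0.552; that argues against it as the whole cause, while Xist at 1.15 (1.11 to 1.18) leaves a smaller change open. At CT34 the share of males cannot be told apart from other causes: Y-linked reads were at 0.5001 of the CT22 level, but Xist, which more females would raise, was at 0.680, and removing the GC and length trend took the Y-linked median log2 CT22 over CT34 from 0.82 to 0.28. Y-linked genes, which a changed share would move alike, differed there, from 0.324 for Ddx3y (0.256 to 0.407) to 0.775 for Kdm5d (0.614 to 0.977). Reads shared between near-identical genes also stay open, since the 7 genes in which multi-mapped reads add at most 10% had a median CT28 over CT40 of 0.689, with 6 of them lower at CT28, and the other 7 had 0.384; circadian time, the factor in the design, was not tested apart from these.

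More genes fitted a 24-h cosine in the true order of the libraries than in others: 196, against 22 for the order CT22, CT28, CT40, CT34, which a steady drift of library quality would favour. That argues against steady drift as the whole cause of the calls, though at an unadjusted p under 0.05 the gap was smaller. By limma it was 1303 genes in the true order against 877, just under the 1.5 times set for the calls. By edgeR it was 1429 against 944, just over that limit. It does not exclude drift from the wider set, since among genes with a 2-fold range the 24-h share was higher in that order (83.4%) than in the true one (80.4%). As many genes were called in 1 of the 3 possible orders, the true one itself, with 22 the highest of the others. With only 3 orders, no share can fall under 0.05. Bias with GC content or length in the calls was not tested.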

How the results depend on the processing

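Alternatives with the 5' or 3' part of transcripts, junction counts, the GC and length trend and a pseudocount of 1 in the cosine model were chosen after seeing the data. The edgeR test, planned for the cosine model, gave way to limma once the deposited unit was seen, and its use on recovered reads was then added. No paired analysis was possible because each time has 1 library and the results come from no test between replicates. Counting all junction reads for the Clock exon was not run, since the junction files hold 1 count per junction; adding junctions within 20 bases and those that skip 2 exons, also chosen after seeing the data, gave 99.4% skipping against 99.3%. Counts are given as the 2-fold range, then CT22 higher and lower than CT34, then CT28 higher and lower than CT40; the main ones were 1184, 282, 366, 112 and 100. Fewer or more genes tested gave 2763, 702, 702, 364 and 307 at a mean of 10 reads and 506, 101, 187, 34 and 44 at 500. A 1.5-fold threshold gave 4006, 1053, 1375, 460 and 559. Removing the GC and length trend gave 777, 157 and 226 for the first 3, and 647 of the main 1184 genes stayed. The 5' parts gave 1780, 445 and 580, and 176 lower at CT28. Deposited values without TMM gave 151 higher and 634 lower at CT22 with a pseudocount of 0.1, and 90 higher at CT22 and 50 higher at CT28 with 1; the median gene then shifts by -0.23 and -0.19 log2 for CT22 over CT34, and the share of calls higher at CT22 goes from 43.5% to 19.2% and 20.8%. That share was 56.8% with total counts. Leaving out 1 library gave 309 (without CT22) to 1088 (without CT28) genes with a 2-fold range. The cosine model called 365 genes with edgeR on recovered reads, 361 with limma-voom and 78 with DESeq2, against 196; its other alternatives gave 134 to 294. The 24-h share was 79.6% at a mean of 500 reads against 80.5%. Junctions shared by all libraries were 64.4% at 10 reads against 48.9%. For tools, units and parts of transcripts the cause was not tested. The direction reversed for 1 named value, Rpl10a, whose log2 CT28 over CT40 was -0.12 with multi-mapped reads, which raise its total 12.0-fold. Over all 3492 comparisons of named genes and lists with an alternative, 2670 stayed within counting error or 0.25 log2, 821 moved further and 1 reversed.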

Other observations

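Some groups have not been described so far. Liver outputs of the clock had a median log2 range of 1.15, above all 10000 random lists, with a 2-fold range in 11 of 18 members and 7 called by the cosine model. Immediate early genes had a median range of 1.02 (percentile 99.7) and a 2-fold range in 5 of 9. Erythroid genes had a median log2 CT28 over CT40 of 0.95 over 4 members (percentile 100), but the globins share most of their reads with one another. PAR bZIP targets of drug metabolism had medians of 0.22 (percentile 97.3) and 0.26 (percentile 99.7) for the pairs, and Alas1, the first enzyme of haem synthesis, went from 20875 at CT22 to 7859 at CT40. Among single genes, Thrsp, a lipogenic regulator, was 5.12-fold higher at CT22 than at CT34 (4.86 to 5.39), the cold-inducible gene Rbm3 went from 361 at CT22 to 122 at CT40, and Cirbp from 125 to 269. Multi-mapped reads bring the total of Rbm3 to 1.54 times its unique reads.

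For the lists that follow, both medians lay within the central 95% of random lists. Median log2 CT22 over CT34 and CT28 over CT40 were -0.42 (percentile 2.62) and 0.05 for fatty acid synthesis, 0.05 and -0.38 (percentile 4.51) for the 3 cold-inducible genes, -0.11 and -0.11 for gluconeogenesis, 0.14 and -0.16 for immediate early genes, -0.05 and 0.13 for the amino acid response, 0.19 and 0.16 for the cell cycle, 0.03 and 0.02 for Kupffer cells, -0.33 and 0.20 for stellate cells, -0.42 (percentile 3.03) and -0.09 for periportal genes, -0.17 and 0.19 for pericentral genes, 0.00 and 0.10 for hepatocytes, 0.03 and 0.11 for mitochondrial respiration and 0.15 and 0.10 for liver outputs of the clock. Few markers passed the filter for cholangiocytes (2), lymphocytes (1) and pancreas (1), and none did for neutrophils or for fat and muscle.

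Within Clock, read density was uneven along the transcript, a feature singled out after its values were seen. Exons 2 to 9 held 158, 133, 127 and 146 reads per kb in time order, exons 10 to 18 held 817, 732, 906 and 990, exon 19 held 105, 78.4, 111 and 170, exons 20 to 22 held 843, 991, 1188 and 1339, and the last exon, exon 23, held 173, 171, 167 and 160. The choice between junctions that share an end rarely differed: of 34034 junctions with such a choice and at least 50 reads at the shared end in each library, 157 differed by 20 points or more between libraries. Junctions of the same choice are counted separately, and the number expected from counting error was not computed. For Atp13a3, the use of the junction from 30315988 to 30321891 on chromosome 16 ran from 19.2% at CT28 (14 of 73 reads) to 68.2% at CT40 (58 of 85). This junction and its alternative were picked because they had the widest spread.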
